A study of Mus musculus with 32 samples.

How the data were processed

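The series measured RNA in hybrid mouse embryonic stem cells (ESCs, day 0) and in induced neurons (iNs, day 10) made from them by doxycycline induction of a Neurog2 (Ngn2) transgene. Per the labels, control cells were Mirg(fl/+) and deletion cells carried the maternal deletion of the microRNA cluster from miR-379 to miR-410. Small RNA libraries (12) and rRNA-depleted RNA libraries (12) had 3 replicates for each cell type and genotype. Ago2 seCLIP libraries (8) came from control iNs that expressed untagged Ago2 or HA-tagged Ago2, with 2 replicates each of the input and of the anti-HA immunoprecipitate.

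The submitters' processing notes name cutadapt 1.4.2, STAR 2.4.1d, RSEM 1.2.30, DESeq2 and SAMtools (the last 2 without a version) and the genome build mm10, without roles or order. Each library's deposited file held the expected counts and posterior mean counts that RSEM estimates, per the file headers, per gene for RNA-seq and per transcript, mature microRNA or hairpin for small RNA-seq. These counts were not scaled to depth and differed in total between libraries. The strand setting and the annotation release were not stated, so counts of genes that overlap on opposite strands, and of near-identical copies, are uncertain. The authors' DESeq2 tables gave, per the file headers, a log2 fold change, an adjusted p-value and a mean normalised count, a signal value averaged over the libraries compared. The deposited CLIP peak lists gave a log2 fold and a −log10 p for each region, of the HA-Ago2 immunoprecipitate over its input or over the immunoprecipitate of untagged Ago2. The CLIP replicates were not kept apart in the deposited lists and the peak caller was not stated, so the CLIP fold values are the authors' and have no replicate check here.

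MicroRNA features were identified by their accessions. Names came from the authors' deposited small RNA tables, in which each microRNA's normalised mean was matched to the counts of 1 accession with a relative tolerance of 1e-08. This named 826 of 1907 accessions, which held 99.99% of the mature microRNA counts. Copies of 1 mature sequence were summed. Gene symbols were read from the files for 52435 of 52636 gene entries. Coordinates came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes. The cluster list held the microRNAs located from Mir379 to Mir410 on chromosome 12, and the upstream list those from Meg3 to Mir379.

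Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjustment with a threshold of 0.05). The comparisons were control iNs against control ESCs, deletion against control in each cell type, and the difference of the deletion's effect between iNs and ESCs (the interaction). Each of the first used its 6 libraries and the interaction used all 12 of the assay. A log2 fold change is given with its standard error (SE), taken as its size divided by the square root of F. CPM values use the scaled library size. The p-values measure only the spread between these libraries.

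The lists of genes and microRNAs, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The rule named the genes of the imprinted domain, the 10 largest rises and 10 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups, and at most 4 members past the threshold per list. Genes with a Gm or Rik symbol were left out of that ranking. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 and adjusted over the lists of 1 comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way without comparing it with other genes, were run beside it. Genes with a deposited peak matched to a cluster microRNA were compared with genes that had other peaks only, with camera and with an exact two-sided permutation of the library labels. Peak lists were intersected with bedtools 2.31.1.

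Alternatives were DESeq2's size factors and the Wald test of DESeq2 1.42.0, no filter beyond a total above 0, all 12 libraries in 1 fit, each library left out in turn, a block on the replicate letter, scaling of small RNA counts to the sum of all features, and other target backgrounds and peak thresholds. Posterior mean counts, copies of a mature sequence kept apart, scaling without the cluster microRNAs, removal of mitochondrial, 7S and ribosomal-RNA-like genes, lists without Mirg, and 2 further target backgrounds were added after seeing the data. Replicate letters A to C recur in every group. In the RNA libraries of the ESC deletion comparison, libraries of the same letter deviated together from their group means (r = 0.348, 0.107 and 0.136, across genes, which are not independent replicates). All were above 0.1, so the letters were taken to pair these libraries. Deletion library C with control library B had r = 0.12, so this pairing is uncertain. Results are from fits without the block unless the block is named. In the other comparisons at least 1 pair had r of 0.1 or below, and the letter was not taken as a pair.

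Each test was first run on simulated counts drawn from the real means with 200 genes changed. The edgeR step recovered 82.8% of genes changed 2-fold and 97.9% of those changed 4-fold for the iN deletion (16046 genes), and 82.5% and 97.9% for the ESC deletion (16177 genes). For control iNs against control ESCs it recovered 87.8% and 99% (16906 genes), and for the interaction 76.8% and 87.8% (17810 genes). For small RNA it recovered 95% and 100% for the iN deletion (437 microRNAs), 88.9% and 98.9% for the ESC deletion (450), 81.4% and 98.9% for iNs against ESCs (498), and 58.9% and 90% for the interaction (538). Unchanged microRNAs called there numbered 5, 2, 5 and 9. Unchanged genes called in the RNA simulations numbered 28 for the iN deletion and 17 for the ESC deletion. They numbered 18 for iNs against ESCs and 7 for the interaction. The changed genes tested numbered 196, 192, 197 and 197 in the same order. In the target test, 624 targets simulated 1.1-fold higher gave a median log2 difference of 0.135 from 4235 other genes, and unchanged ones a difference of -0.003. Within each group, all 24 pairs of libraries differed by more than counting error (chi-square per degree of freedom from 2.86 to 128.38), so no library was a copy of another.

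A count of 0 over a group was read as at most 3 counts over that group. Reads were not treated as independent molecules, so these floors cover counting error only. Gene-level CLIP changes were not computed per replicate. The authors' deposited table of the iN deletion in RNA-seq listed 3713 genes past its threshold, of which 3375 were also called here in the same direction. The authors' deposited table of the ESC deletion listed 499 such genes, of which 268 were also called. The authors' deposited small RNA tables list copies of a mature sequence apart. By name they held 436 microRNAs past the threshold for control iNs against control ESCs (407 also called) and 132 for the iN deletion (128 also called).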

Results

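The libraries came from mouse embryonic stem cells (ESCs) and from neurons induced from them by Neurog2 (iNs), each as control and with the maternal copy of the microRNA cluster from miR-379 to miR-410 deleted. Small RNA-seq and rRNA-depleted RNA-seq had 3 libraries per group. RNA libraries held 14904735 to 21499106 counts and small RNA libraries 3038112 to 4216346, of which mature microRNAs made up 18.0 to 27.9% in ESCs, 37.0 to 38.6% in control iNs and 29.0 to 30.1% in deletion iNs. The most abundant mature microRNA was miR-16-5p in ESCs (10.4 to 14.7%) and miR-182-5p in iNs (up to 25.8%). Mitochondrial genes held 3.42 to 4.38% of RNA counts in control iNs, 2.45 to 3.6% in deletion iNs, 1.99 to 2.27% in control ESCs and 1.47 to 1.84% in deletion ESCs. Genes for 7S RNA and ribosomal-RNA-like transcripts held 12.73 to 14.16% in ESCs and 6.93 to 8.23% in iNs. Lists of genes and microRNAs were fixed before the data were examined. All p-values measure only the spread between these libraries.

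The deleted locus was examined first in each library. Mirg, the host transcript of the cluster, had 932, 672 and 789 counts in the control ESC libraries and 0 in each of the 3 deletion ESC libraries, at least 837-fold lower. In control iNs it had 455, 685 and 648 counts and in deletion iNs 2, 0 and 2 (33.5 ± 3.69 against 0.0673 ± 0.0583 CPM, mean ± SD, n = 3; log2 fold change −8.80 ± 0.24 SE). Cluster microRNAs made up 12.104 to 12.792% of mature counts in control iNs and 0.016 to 0.02% in deletion iNs. In ESCs the share was 7.895 to 8.65% in controls and 0.008 to 0.012% with the deletion. All 51 cluster microRNAs tested fell in each cell type, in every case with no overlap between the 3 control and 3 deletion libraries.

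**Figure D1:**
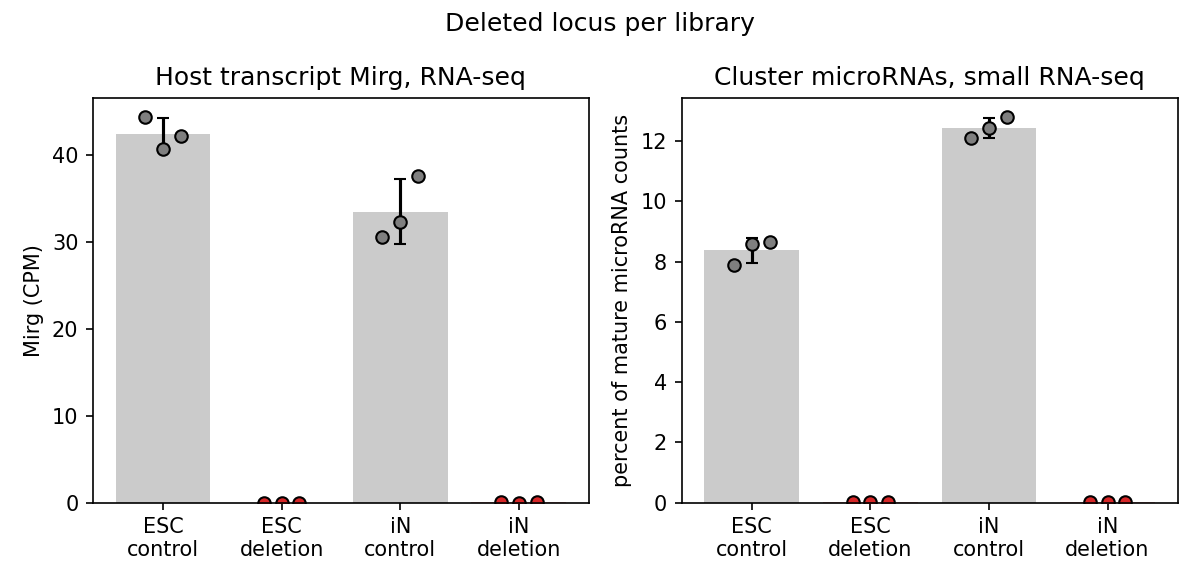
Level of Mirg (counts per scaled library) and share of mature microRNA counts that lay in the cluster from miR-379 to miR-410, per library. Bars are means, error bars SD and points libraries (n = 3 per group).

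In iNs, 24 of the 51 cluster microRNAs had 0 counts with the deletion, 7 had 1 to 3 and 20 had more. With counts of 3 or fewer set to 3, the median fall was 261-fold (range 12 to 2040), and the summed counts of the list fell from 539240 to 524. In ESCs, 22 had 0 counts, 10 had 1 to 3 and 19 had more, the median fall was 213-fold (13.7 to 2500) and the sum fell from 234511 to 297. miR-382-5p went from 174934 to 235 counts in iNs and from 28413 to 82 in ESCs. miR-379-5p, the first microRNA of the cluster, went from 61214 to 30 and from 42226 to 31. miR-411-5p fell by 10.92 ± 0.19 log2 units in iNs and by 10.50 ± 0.23 in ESCs, and miR-381-3p fell by 10.77 ± 0.20 in iNs (SE, n = 3 per group). miR-410-3p, the last of the cluster, had 0 counts in both deletion groups against 375 and 224 in controls. miR-666-3p was at least 390-fold lower in iNs, and miR-543-3p at least 470-fold lower in ESCs.

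Among the genes beside the deleted cluster, 3 noncoding transcripts had calls in opposite directions in the 2 cell types, and Dlk1 fell in iNs. Meg3, the long noncoding RNA at the start of the maternal transcript, rose in iNs from 1360 to 2010 CPM (log2 fold change 0.56 ± 0.10) and Rian, which hosts snoRNAs, rose by 0.27 ± 0.06 (SE, n = 3 per group). In ESCs Meg3 fell by 0.38 ± 0.05 and Rian by 0.38 ± 0.07, calls that were lost for Meg3 without deletion ESC library B and with all 12 libraries in 1 fit, and for Rian in 5 alternatives. B830012L14Rik, a noncoding transcript of the domain, rose by 0.85 ± 0.11 in iNs and fell by 0.66 ± 0.06 in ESCs. Dlk1, the paternally expressed gene of a Notch-like protein, fell by 1.28 ± 0.14 in iNs (10.5 to 4.3 CPM) and did not pass in ESCs (−0.35 ± 0.12, adjusted p = 0.198, edgeR quasi-likelihood test with Benjamini-Hochberg correction, n = 3 per group). Dio3 (0.09 and −0.79) and Begain (0.28 and −0.47) did not pass in iNs or ESCs. As a list, the Dlk1-Dio3 domain genes fell in ESCs relative to other genes (4 of 8 fell, 5 when adjusted over the list alone, median log2 fold change −0.43, adjusted p = 8.07e-08, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.0446 with an estimated correlation. The list holds the deleted Mirg, and without it 3 of 7 fell (median −0.38, adjusted p = 4.22e-05, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.0528 with an estimated correlation. In iNs 3 of 9 rose and 2 fell, Mirg and Dlk1 (4 and 2 over the list alone), and the list was not called (adjusted p = 0.615, camera with Benjamini-Hochberg correction, 6 libraries, median 0.09; 0.166 and 0.18 without Mirg). Rtl1 overlaps a transcript on the other strand and held few counts, so its change is uncertain.

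**Figure D2:**
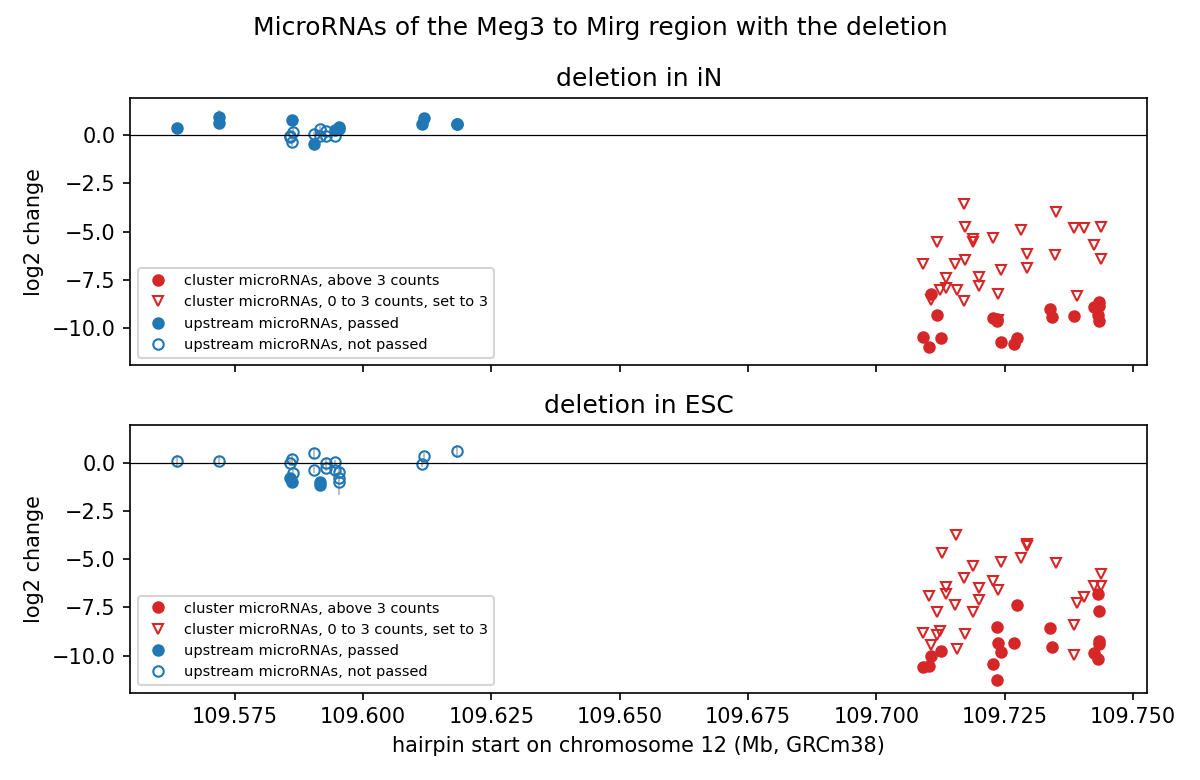
Change of cluster and upstream microRNAs along chromosome 12 with the deletion in iNs and ESCs (n = 3 per group). For cluster microRNAs, circles are ratios above 3 counts and open triangles are set to 3 counts. For the upstream part, points are fitted log2 fold changes with SE, filled where past the threshold.

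How far the iNs had moved from the ESCs was asked in the controls. The induced cells carried high levels of the RNAs of neurons, their synapses and their ion channels and had lost those of stem cells and of dividing cells. Of 17247 genes tested, 7571 rose and 7781 fell. All 24 pan-neuronal genes rose (median log2 fold change 5.70), among them Dcx, a microtubule protein of migrating neurons (10.36 ± 0.16), and Snap25, of the vesicle fusion complex (9.08 ± 0.18; SE, n = 3 per group). All 21 neuronal ion channel genes rose (median 5.46), led by the sodium channel Scn9a (9.76 ± 0.09) and the potassium channel Kcna2 (9.49 ± 0.13). Of 27 glutamatergic synapse genes 26 rose and 1 fell (median 3.95), including the AMPA receptor subunit Gria2 (11.17 ± 0.14) and the vesicular glutamate transporter Slc17a6 (7.74 ± 0.15). Of 19 neurogenic transcription factors 18 rose (median 5.08), among them Myt1 (9.18 ± 0.15), Nhlh1 (8.20 ± 0.16) and Isl1 (8.09 ± 0.15). Of 26 axon guidance genes 20 rose and 4 fell (median 3.22), with the plexin Plxna4 up by 8.17 ± 0.10. With camera the adjusted p-values of these 5 lists were from 7.47e-10 to 0.000773 (Benjamini-Hochberg correction, 6 libraries), and with an estimated correlation 0.13 for all but the transcription factors (0.0497).

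Stem cell genes moved the other way. Of 24 pluripotency genes 23 fell and 1 rose (median −7.72), among them Sox2 (−10.87 ± 0.14) and the Nodal co-receptor Tdgf1 (−11.20 ± 0.12), and Fgf4, the growth factor that primes ESCs, was at least 2450-fold lower. All 20 proliferation genes fell (median −7.16), with the topoisomerase Top2a down by 8.85 ± 0.09 and Mki67 by 8.23 ± 0.08, and all 13 histone genes fell (median −5.75), with Hist1h1b down by 10.05 ± 0.15. Fibroblast genes (10 of 14 fell and 2 rose, median −4.85, adjusted p = 0.0171, camera with Benjamini-Hochberg correction, 6 libraries) and endoderm and mesoderm genes (10 of 11 fell and 1 rose, median −4.06, adjusted p = 0.012) were lower, both 0.13 with an estimated correlation. Fn1, an extracellular matrix protein, fell by 7.73 ± 0.08. The pluripotency, proliferation and histone lists had adjusted p from 2.14e-05 to 5e-08 with camera and Benjamini-Hochberg correction over 6 libraries, and 0.0496, 0.0496 and 0.205 with an estimated correlation. All 16 cholesterol synthesis genes rose (median 2.20, 1.48e-06, 0.205 with an estimated correlation), among them Dhcr7, which makes cholesterol from its last precursor (3.28 ± 0.07). Of 13 mitochondrially encoded genes 10 rose, 9 when adjusted over the list alone (median 0.72, 0.0338, 0.461 with an estimated correlation).

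Lists not called in this comparison held members that moved both ways. Of the Dlk1-Dio3 genes 6 of 9 rose and 3 fell (median 0.97), with Meg3 up by 2.16 and Dio3, a thyroid hormone deiodinase, by 3.66. Paternally expressed imprinted genes rose in 19 and fell in 9 of 30 (Nap1l5 8.45 ± 0.19, Slc38a4 −8.02 ± 0.13) and maternally expressed ones rose in 13 and fell in 10 of 25 (0.45; Phlda2 −5.42 ± 0.24). Of 9 GABAergic and other transmitter genes 7 rose and 2 fell (3.76). Neural progenitor genes fell in 9 and rose in 3 of 12 (−3.22; Otx2 −7.22 ± 0.15), and glial genes rose in 5 and fell in 3 of 8 (1.90), with the glutamate transporter Slc1a2 up by 7.26 ± 0.13 and Slc1a3 down by 8.89 ± 0.16. Immediate early genes fell in 9 and rose in 2 of 12 (−1.21; Nr4a1 −4.75 ± 0.20), p53 and stress genes fell in 10 and rose in 7 of 20 (−0.26; Pmaip1 −4.45 ± 0.10, Atf5 2.77 ± 0.08) and microRNA pathway genes fell in 11 and rose in 4 of 17 (−0.51; Lin28a, a blocker of let-7 processing, −4.09 ± 0.07, and the Argonaute gene Ago4 3.66 ± 0.20). In the other lists of this comparison, adjustment over the list alone gave the same counts.

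MicroRNAs also separated the 2 cell types. Neurons held more of most microRNAs known from brain and less of the stem cell families. Of 523 microRNAs tested 217 rose and 231 fell. Scaling to all features of the file shifted the median by 0.72, with 246 up and 181 down, and DESeq2's size factors shifted it by 0.19, with 232 up and 223 down. Of 18 neuronal microRNAs 14 rose and 3 fell (median 3.76), with miR-137-3p up by 9.21 ± 0.20 (SE, n = 3 per group, 55.4 to 32800 CPM). Of 12 let-7 microRNAs 9 rose and 1 fell (median 1.83), with let-7b-5p up by 5.76 ± 0.25. All 22 pluripotency microRNAs fell (median −5.45), among them miR-291a-3p (−8.20 ± 0.62) and miR-302b-3p (−6.43 ± 0.23), as did 24 of 26 of the miR-17 to 92 family (median −3.19; miR-18b-5p −5.89 ± 0.20) and all 34 from the Sfmbt2 intron (median −4.87; miR-466m-3p −7.72 ± 0.41). These 5 lists had adjusted p from 2.06e-09 to 0.00949 (camera with Benjamini-Hochberg correction, 6 libraries), and from 0.239 to 0.315 with an estimated correlation. Cluster microRNAs (27 rose and 17 fell of 56, median 0.39) and upstream microRNAs (14 rose and 5 fell of 24, 0.61) were not called, nor were microRNAs of other cell types (2 rose and 10 fell of 14, −1.04). miR-487b-3p of the cluster rose by 3.42 ± 0.18, miR-411-3p fell by 3.62 ± 0.36, and miR-770-3p of the upstream part rose by 4.60 ± 0.24.

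What the deletion did to the RNA of neurons was asked next. Deletion iNs had less RNA of the cholesterol pathway and of a joint list of p53 and stress response genes. They had more of Neurog2 and of many synapse and channel genes. For the changes below, a difference in line, medium, handling or transgene level between control and deletion cultures cannot be told apart from the genotype. No list call in this comparison held with an estimated correlation. With fry, called lists had adjusted p from 0.00101 to 0.00476 (Benjamini-Hochberg correction, 6 libraries), except mitochondrially encoded genes (0.251). Fry also passed lists that camera did not call, such as GABAergic and other transmitter genes (0.00101) and fibroblast genes (0.00422). Of 16028 genes tested 1981 rose and 2128 fell, with 276 and 238 changed at least 2-fold. The median size of a change was 0.40 log2 units.

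Cholesterol synthesis genes fell in 15 of 16 (median −0.54, adjusted p = 4.32e-16, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.193 with an estimated correlation. Mvd fell by 0.91 ± 0.07, Cyp51 by 0.73 ± 0.05 and Msmo1, which demethylates sterols, by 0.72 ± 0.05 (SE, n = 3 per group), and Insig1, the sterol sensor, by 0.67 ± 0.07. Of 20 p53 and stress genes 11 fell and 1 rose (2 over the list alone; median −0.42, adjusted p = 1.24e-05, 0.193 with an estimated correlation). That list joins p53 targets with other stress genes, and these parts were not tested apart. Among those that fell were Chac1, which degrades glutathione (−2.36 ± 0.20), Atf5 (−1.40 ± 0.07), Trib3 (−1.22 ± 0.20) and Sesn2 (−1.19 ± 0.10). Among the largest falls were Cth, which makes cysteine (−4.82 ± 0.33, 15 to 0.527 CPM), Phgdh, the first enzyme of serine synthesis (−3.67 ± 0.15, 34.1 to 2.67 CPM), and the amino acid transporter Slc7a3 (−3.57 ± 0.15, 43.1 to 3.62 CPM). The glycoprotein hormone gene Stc2 fell by 2.58 ± 0.18. Among the largest rises were Txnip, which binds thioredoxin and curbs glucose uptake (2.73 ± 0.28, 3.42 to 23.1 CPM), the neuropeptide gene Nts (2.39 ± 0.12), Cpt1a, which admits fatty acids to mitochondria (2.32 ± 0.11), and Sall3 (2.12 ± 0.13).

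**Figure D3:**
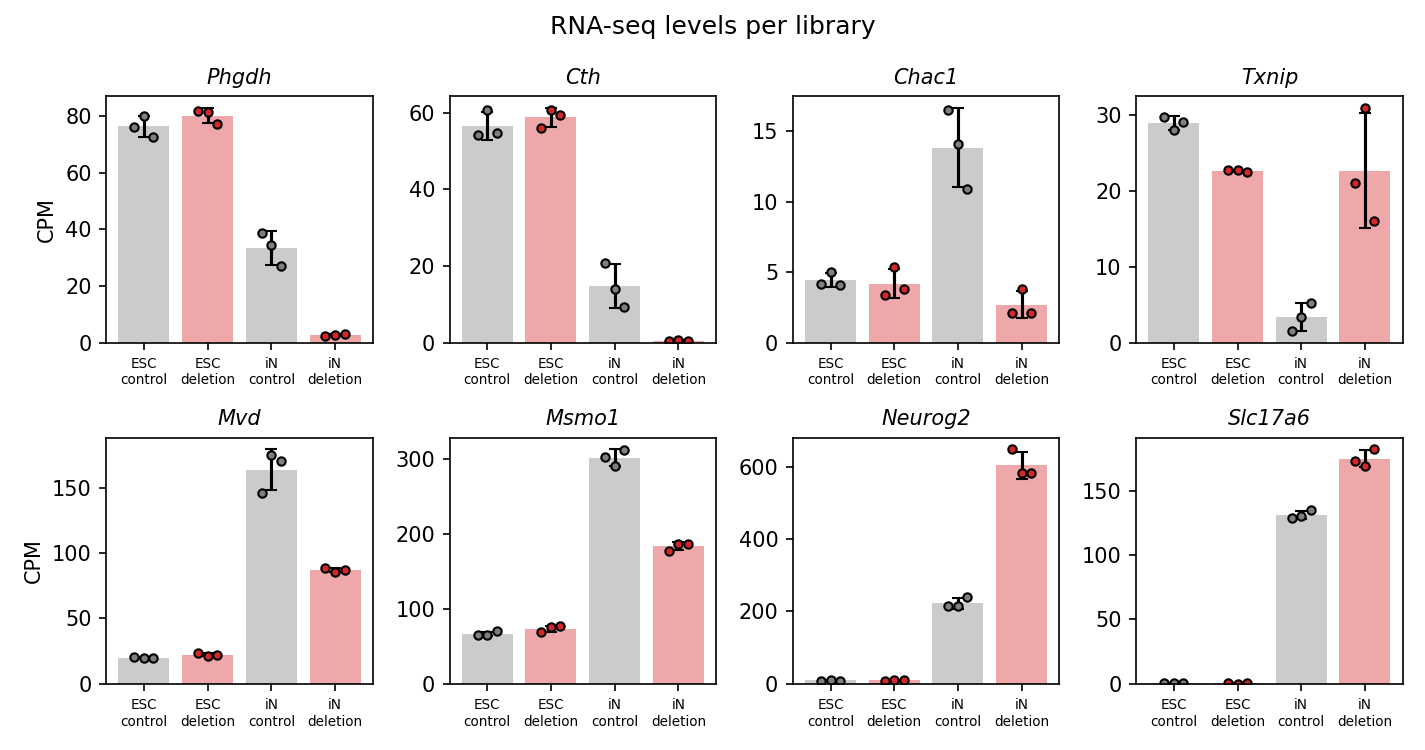
CPM of 8 genes in each RNA library: Phgdh, Cth, Chac1, Txnip, Mvd, Msmo1, Neurog2 and Slc17a6. Bars are means with SD and points libraries (n = 3 per group).

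Neuronal lists rose on balance by small amounts. Pan-neuronal genes rose in 10 of 24 with none falling (13 and 3 over the list alone; median 0.13, adjusted p = 0.00104, camera with Benjamini-Hochberg correction, 6 libraries; adjusted p = 0.308 with an estimated correlation), including the adhesion molecule Ncam1 (0.45 ± 0.06), Syp of synaptic vesicles (0.39 ± 0.05) and Rbfox3 (0.37 ± 0.06). Glutamatergic synapse genes rose in 14 and fell in 4 of 28 (18 and 4 over the list alone; median 0.19, 0.000107, 0.193 with an estimated correlation), with the postsynaptic adhesion molecule Nlgn3 up by 0.84 ± 0.07 and the scaffold Shank1 by 0.82 ± 0.16. Ion channel genes rose in 12 and fell in 3 of 21 (13 and 3; median 0.17, 0.00645, 0.308 with an estimated correlation), with Kcnq3 of the M current up by 0.54 ± 0.06, Scn1a by 0.53 ± 0.06 and Kcna2 down by 0.52 ± 0.06. Axon guidance genes rose in 10 and fell in 3 of 26 (10 and 4; median 0.12, 0.00927, 0.209 with an estimated correlation), with Epha5 up by 0.89 ± 0.11 and Plxna2 by 0.68 ± 0.06, and the repellent Sema3a down by 1.02 ± 0.11. Neurogenic transcription factors rose in 8 and fell in 4 of 20 (10 and 4; median 0.27, 0.0206, 0.308 with an estimated correlation). Neurog2, whose transgene drives the induction and may hold part of the counts, rose by 1.44 ± 0.06 (228 to 618 CPM), Insm1 by 0.84 ± 0.12 and Nhlh1 by 0.83 ± 0.07. Glial genes rose in 3 of 6 (median 0.34, 0.0441, 0.27 with an estimated correlation and 0.0501 with a replicate block), among them S100b (1.75 ± 0.27). Among GABAergic and other transmitter genes 4 rose and 1 fell of 9 (median 0.08, not called), with the choline transporter Slc5a7 (0.80 ± 0.18) and the vesicular acetylcholine transporter Slc18a3 (0.70 ± 0.07) up.

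Pluripotency genes fell in 8 and rose in 2 of 14 (9 and 2 over the list alone; median −0.77, adjusted p = 0.00323, camera with Benjamini-Hochberg correction, 6 libraries; adjusted p = 0.193 with an estimated correlation), with Dppa4 down by 1.22 ± 0.16 and Lin28a by 0.88 ± 0.10. Mitochondrially encoded genes fell in 6 of 13 (8 over the list alone; median −0.39, 0.0017, 0.495 with an estimated correlation), with mt-Nd3 down by 0.73 ± 0.11, in libraries whose mitochondrial share was 2.45 to 3.6% against 3.42 to 4.38% in controls. Lists not called were the paternally expressed imprinted genes (4 rose and 10 fell of 30, median 0.02), with Nnat, a membrane protein of neurons, down by 1.51 ± 0.08, and the maternally expressed ones (6 and 6 of 23 with Mirg, 7 and 6 over the list alone, 0.04), with H19 up by 1.90 ± 0.17. Neural progenitor genes rose in 3 and fell in 1 of 10 (0.37; Pax6 0.92 ± 0.16, Vim −0.45 ± 0.05) and immediate early genes rose in 2 and fell in 3 of 12 (4 and 3 over the list alone, −0.02; Jun 1.27 ± 0.11, Egr1 −1.79 ± 0.26). Fibroblast genes rose in 2 of 7 (3 over the list alone, 0.13; Col6a1 1.84 ± 0.22), endoderm and mesoderm genes rose in 1 and fell in 1 of 5 (2 and 1, 0.41; Tal1 1.06 ± 0.15) and proliferation genes rose in 1 of 18 (0.06; Ccna2 1.28 ± 0.26). MicroRNA pathway genes rose in 3 and fell in 3 of 17 (4 and 4, −0.02; Ago4 0.57 ± 0.12, Trim71 −0.56 ± 0.06), and 1 of 12 histone genes fell (0 over the list alone, −0.03). Counts over the list alone not given here were the same.

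**Figure D4:**
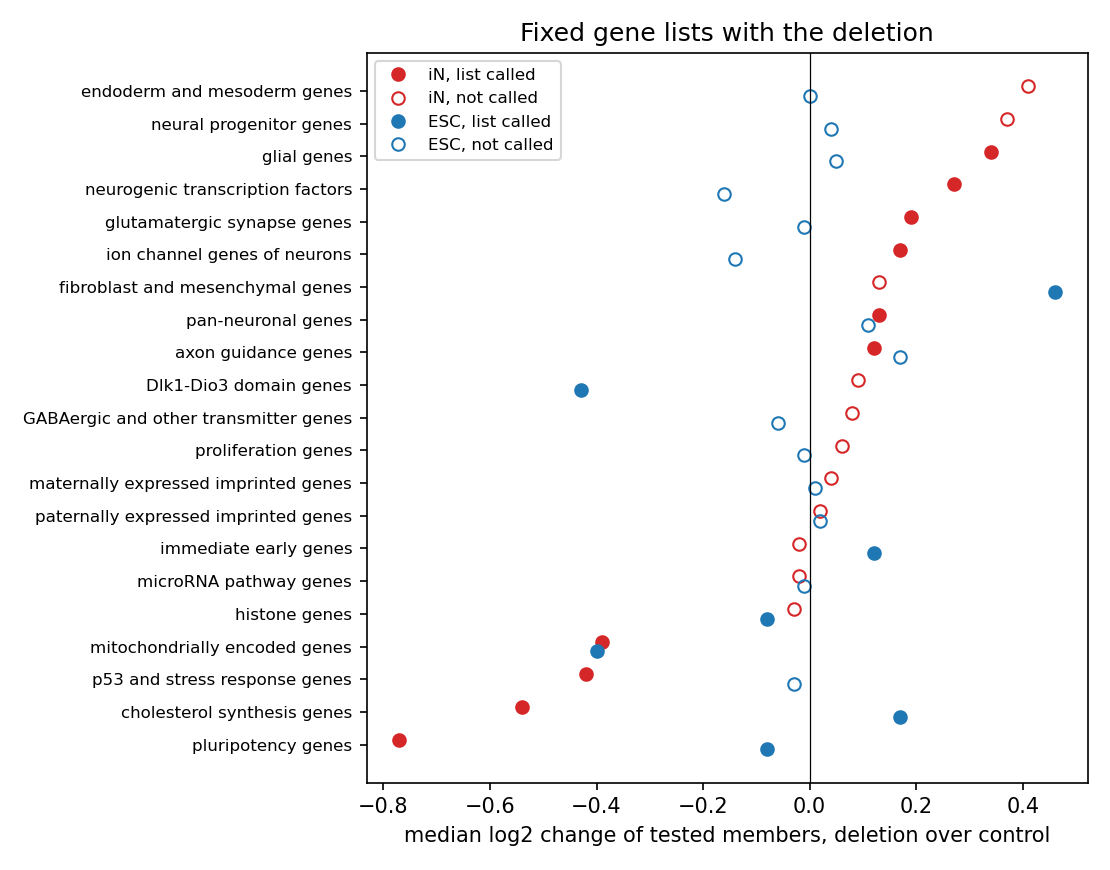
Median log2 fold change of each gene list with the deletion in iNs (red) and ESCs (blue), n = 3 per group. Filled points are lists called by camera with a preset correlation. No called list changed direction with DESeq2's size factors.

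In ESCs the deletion changed fewer genes, and few of them 2-fold. Stem cells without the cluster had slightly more RNA of fibroblast and mesenchymal genes and slightly less of a few pluripotency regulators. Of 16185 genes tested 221 rose and 88 fell, 309 in all, with 2 and 7 changed at least 2-fold. With a replicate block, the letters being taken as pairs, 518 rose and 501 fell, 1019 in all, and these included the 309. The count thus rests on this choice. Other calls in ESCs are from the fit without the block, and some genes that did not pass may pass with it. Leaving out control library A, B or C left 137, 91 and 155, and leaving out deletion library B or C left 90 and 160. Fibroblast and mesenchymal genes rose in 6 of 14 (8 over the list alone; median 0.46, adjusted p = 2.23e-08, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.0504 with an estimated correlation. Col1a1 rose by 0.75 ± 0.07, and Tagln and Acta2 of smooth muscle actin fibres by 0.61 ± 0.05 each (SE, n = 3 per group). Among the largest rises were Ankrd26 (1.05 ± 0.07, 13.8 to 28.6 CPM), the keratin genes Krt19 (0.84 ± 0.09) and Krt18 (0.77 ± 0.05), and H19, a maternally expressed noncoding RNA (0.77 ± 0.06). Among the largest falls were the deubiquitinase Usp26 (−1.61 ± 0.07, 28.1 to 9.22 CPM), A2m (−1.05 ± 0.11) and Ephx2 (−0.82 ± 0.07), and the Nodal inhibitor Lefty1 fell by 0.71 ± 0.06.

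Pluripotency genes fell in 4 of 24 (9 over the list alone; median −0.08, adjusted p = 0.000112, camera with Benjamini-Hochberg correction, 6 libraries; adjusted p = 0.0504 with an estimated correlation), with the self-renewal factor Tfcp2l1 down by 0.32 ± 0.04. Cholesterol synthesis genes, lower in iNs, rose in 3 of 16 in ESCs (9 over the list alone; median 0.17, 1.49e-08, 0.0446 with an estimated correlation, a call lost once Mirg was left out of the lists), and Fdps, the largest at 0.29 ± 0.05, was lost in some alternatives. Mitochondrially encoded genes fell in 1 of 13 (9 over the list alone; median −0.40, 1.49e-08, 0.144 with an estimated correlation), in libraries whose mitochondrial share was 1.47 to 1.84% against 1.99 to 2.27%. Immediate early genes rose in 3 and fell in 1 of 14 (median 0.12, 0.00899, 0.137 with an estimated correlation), with Fosl2 up by 0.64 ± 0.05. Histone genes were called lower with 0 of 13 past the edgeR threshold (1 unadjusted, 0 with DESeq2; median −0.08, 0.031, 0.576 with an estimated correlation). Lists not called included paternally expressed imprinted genes (2 rose and 2 fell of 28, 3 and 2 over the list alone, median 0.02; Peg10 0.41 ± 0.04), maternally expressed ones (1 and 3 of 25 with Mirg, 0.01) and pan-neuronal genes (1 rose of 23, 3 rose and 1 fell over the list alone, 0.11). Axon guidance genes rose in 2 of 23 (5 rose and 1 fell over the list alone, 0.17), neural progenitor genes in 2 of 10 (3 and 2; Vim 0.54 ± 0.04, Nes 0.40 ± 0.04), and 1 of 6 GABAergic and other transmitter genes fell. With edgeR, 0 passed of 23 glutamatergic synapse genes (4 unadjusted, 1 fell over the list alone), 16 ion channel genes (3 unadjusted, 2 fell over the list alone, median −0.14) and 11 endoderm and mesoderm genes (7 unadjusted, 1 fell over the list alone). The same test passed 0 of 12 neurogenic transcription factors (3 unadjusted), 6 glial (1), 20 proliferation (1), 20 p53 and stress (7) and 17 microRNA pathway genes (3). DESeq2 passed 0 in each of these lists but 1 p53 and stress gene.

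Beyond the cluster, the deletion's effect on other microRNAs was asked in iNs. Neurons without it had more of several neuronal and upstream microRNAs and less of the pluripotency microRNAs. Of 433 microRNAs tested 73 rose and 105 fell. The falls hold the 51 of the cluster and miR-3072-3p, which lies past Mir410 within Mirg and had 0 counts with the deletion. Without control iN library A or B 42 rose in each case, and with all 12 libraries in 1 fit 43 rose. With scaling to all features of the file 33 rose and 182 fell, cluster included, with a median shift of −0.28. Of 20 neuronal microRNAs 11 rose and 0 fell (13 over the list alone; median 0.40, 0.12 with all features, where 7 rose and 2 fell; adjusted p = 0.000246, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.233 with an estimated correlation. miR-138-1-3p rose by 1.09 ± 0.18 and miR-129-5p by 0.94 ± 0.12 (SE, n = 3 per group). Upstream microRNAs rose in 10 and fell in 1 of 23 (median 0.24, which flips to −0.03 with all features, where 5 rose and 6 fell; 0.00872, 0.291 with an estimated correlation), among them miR-1188-5p (0.88 ± 0.13, 201 to 370 CPM) and miR-540-3p (0.76 ± 0.11). Pluripotency microRNAs fell in 12 of 13 (13 over the list alone; median −1.06, −1.34 with all features; 0.00872, 0.512 with an estimated correlation), with miR-302d-3p down by 1.35 ± 0.14 and miR-291a-5p by 1.21 ± 0.21. Of 12 let-7 microRNAs 2 rose and 1 fell (2 and 0 over the list alone; median 0.09, which flips to −0.18 with all features, not called). The miR-17 to 92 family fell in 8 of 19 (median −0.15, −0.45 with all features, where 11 of 18 fell, not called), with miR-106a-5p down by 1.48 ± 0.17 and miR-20b-5p by 1.42 ± 0.11. With edgeR 0 of 12 microRNAs of the Sfmbt2 intron passed (2 unadjusted, 0 with DESeq2; 3 fell with all features), and 3 of 11 microRNAs of other cell types fell (miR-133a-3p −0.43 ± 0.10; median −0.32, −0.65 with all features, where 9 of 12 fell). Among the largest rises were miR-216b-3p (2.05 ± 0.22), miR-6240 (1.67 ± 0.13), miR-217-5p (1.66 ± 0.14) and miR-216a-5p (1.52 ± 0.13).

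The deletion's effect on microRNAs of ESCs was asked in the same way. Of 450 tested 11 rose and 62 fell, the falls again with the 51 of the cluster and miR-3072-3p. Without the filter 30 rose and 88 fell, and with all 12 libraries in 1 fit 21 rose and 81 fell. Without control ESC library A, B or C 6, 3 and 6 rose, and without deletion ESC library B or C 4 and 3 rose. The number outside the cluster thus depends on the setting, and with a replicate block, though the letters were not taken as pairs here, 60 rose and 119 fell. Scaling to all features shifted the median by 0.19. Upstream microRNAs fell in 4 of 22 (median −0.19, 0.00 with all features, where 1 fell), with miR-337-3p down by 0.79 ± 0.17, a call lost in 2 alternatives. The list from the Sfmbt2 intron was called higher, with 3 of 35 past the threshold (0 over the list alone; median 0.19, 0.47 with all features, where 0 of 36 passed with edgeR; adjusted p = 0.00693, camera with Benjamini-Hochberg correction, 6 libraries), with adjusted p = 0.811 with an estimated correlation and 0.0647 with a replicate block. Among microRNAs of other cell types 2 of 14 fell, both miR-142a arms. With edgeR 0 passed of 13 neuronal (2 unadjusted, 0 with DESeq2; median −0.07, which flips to 0.11 with all features), 10 let-7 (1 and 0; −0.02, which flips to 0.17), 22 pluripotency (7 and 4; −0.44) and 28 miR-17 to 92 microRNAs (6 and 1; −0.23). miR-21a-3p rose by 0.90 ± 0.15.

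Small RNA libraries also held fragments of other transcripts. In deletion iNs mitochondrial rRNA held 6.19 ± 0.29% of counts against 1.80 ± 0.13% in controls, mitochondrial tRNA 8.23 ± 0.69% against 4.37 ± 0.66% and Y RNA 3.75 ± 0.089% against 1.60 ± 0.11% (mean ± SD, n = 3). Of 22 mitochondrial tRNAs tested 7 rose and 7 fell (median 0.08). Of 220 snoRNAs 1 rose and 156 fell among non-microRNA genes (median −0.94), and 8 of 10 in the imprinted domain fell. In ESCs the control and deletion shares were 0.18 and 0.208% for mitochondrial rRNA, 3.07 and 1.82% for mitochondrial tRNA and 0.339 and 0.325% for Y RNA.

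Whether the deletion's effect differed between the 2 cell types was tested as an interaction over 12 libraries. The deletion's effect on cholesterol synthesis genes was lower in neurons than in stem cells, and its effect on Meg3 and Rian was higher. Of 18299 genes tested 917 differed upward in iNs and 1556 downward, and without deletion iN library B 856 and 907. The log2 difference was −0.74 in the median for cholesterol synthesis genes (15 of 16 lower, 16 over the list alone, adjusted p = 6.1e-22, camera with Benjamini-Hochberg correction, 12 libraries, 0.0131 with an estimated correlation) and −0.48 for p53 and stress genes (9 of 20 lower and 1 higher, 10 and 1 over the list alone, 2.3e-05, 0.0131). Mvd differed by −1.06 ± 0.10, Chac1 by −2.29 ± 0.32, Atf5 by −1.43 ± 0.14, Phgdh by −3.74 ± 0.16, Slc7a3 by −3.60 ± 0.16 and Cth by −4.87 ± 0.37 (SE, n = 3 per group). Dlk1-Dio3 genes were higher in 3 and lower in 1 of 9 (6 and 1 over the list alone; median 0.74, 0.00896, 0.179 with an estimated correlation; 0.69 and 0.014 without Mirg), with Meg3 at 0.92 ± 0.15, Rian at 0.64 ± 0.10 and Dlk1 at −0.95 ± 0.19. Glutamatergic synapse genes were higher in 7 and lower in 2 of 28 (12 and 3; median 0.34, 0.0139, 0.252 with an estimated correlation) and ion channel genes higher in 5 of 21 (6; median 0.11, 0.0339, 0.268), with Kcnq3 at 0.75 ± 0.11. Txnip (3.08 ± 0.34), Cpt1a (2.42 ± 0.14) and Neurog2 (1.35 ± 0.12) were higher. The other 16 lists were not called.

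Scaling to all features shifted the median of the microRNA interaction by −0.40, with 1 upward and 47 downward. Of 541 microRNAs 11 differed upward and 19 downward, 30 in all, which became 18, 17 and 19 without control ESC library A, control iN library A and deletion iN library B. Upward differences were 2 without control iN library A or deletion iN library B, and 4 without control ESC library A or C, deletion ESC library B or deletion iN library C. They were 5 without control ESC library B, deletion ESC library C or control iN library B, and 6 without deletion iN library A. Neuronal microRNAs were higher in 3 of 19 (7 over the list alone; median 0.54, 0.12 with all features, where 0 passed with edgeR; adjusted p = 0.000984, camera with Benjamini-Hochberg correction, 12 libraries), with adjusted p = 0.11 with an estimated correlation. Upstream microRNAs were higher in 2 of 25 (5 over the list alone; median 0.45, 0.04 with all features, where 0 passed with edgeR; 0.000984, 0.11 with an estimated correlation). Pluripotency microRNAs were lower in 3 of 22 (5; median −0.56, −1.04 with all features, where 8 of 23 were lower; 0.0452, 0.694 with an estimated correlation), among them miR-291a-5p (−1.27 ± 0.27), and miR-20b-5p differed by −1.50 ± 0.26 and miR-106a-5p by −1.25 ± 0.20.

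Ago2 binding was mapped by seCLIP in control iNs, and the fold values are the authors'. The deposited lists gave 22400 regions of median length 32 bp with a median log2 fold of 2.22 over input and −0.13 over the immunoprecipitate of untagged Ago2. Of the deposited regions, 1428 (6.4%) passed 2-fold and a −log10 p of 3 over the untagged immunoprecipitate, against 72.0% over input. Deposited folds were higher at microRNA hairpin loci, counted on either strand. There 210 regions lay over 168 hairpins with a median log2 fold of 2.8 over untagged Ago2, against −0.15 elsewhere, and Mir96 had the largest (8.39). Over the cluster, 17 regions covered 15 hairpins with a median of 3.31. The authors matched 874 regions in 634 genes to microRNAs of the cluster and to miR-3072-3p, listed as 33 entries of which 3 join 2 names each, most to miR-495-3p (88) and miR-666-3p (65). Zbtb7a (5.82) and the neurogenic factor Neurod1 (5.48) had the largest deposited folds among them. Matches did not follow abundance. In control iNs miR-495-3p had 203 summed counts and miR-666-3p 1694, while miR-382-5p, with 174934, had 13 matched regions. The test of target genes did not weight matches by abundance.

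Whether genes with matched regions rose when the cluster was lost was tested against genes with other regions only. All deposited regions had a median log2 fold of −0.13 over untagged Ago2, against 1.58 for matched regions. Genes with other regions only thus need not be bound by Ago2. A background added later kept only other genes with a region at least 2-fold over untagged Ago2. Against it the median log2 difference was −0.039 in iNs (1269 others) and −0.004 in ESCs (1261 others), and neither passed with camera. Against all genes with other regions only, and with all matched regions, no difference passed in iNs or ESCs. In iNs the median log2 fold change was −0.043 for 624 target genes and −0.021 for 4230 others, a difference of −0.022 (camera p = 0.586 and exact permutation p = 0.4 over the 6 libraries, where the permutation cannot give a p below 0.1 and so decides nothing). Of the targets 14.4% rose and 22.3% fell, against 12.9% and 18.3% of the others. In ESCs the difference was −0.019 (617 against 4202 genes, camera p = 0.243 and exact permutation p = 0.7 over the 6 libraries). There the camera test passed, toward lower levels of the targets, with stricter regions (−0.041) and with genes of 2 or more matched regions (−0.059), and the difference turned to 0.006 without deletion ESC library A. Target genes moved both ways in iNs: Slc24a2, a calcium exchanger with a miR-539-5p match, rose by 0.94 ± 0.06 and Rgs8 by 1.05 ± 0.08, and Bcat1, a branched-chain amino acid transaminase with a miR-495-3p match, fell by 1.26 ± 0.07 and the reelin receptor Vldlr by 1.00 ± 0.06 (SE, n = 3 per group). The match of Slc24a2, miR-539-5p, was not among the cluster microRNAs tested in iNs. Of genes with the most matched regions, Snhg11 (7) rose by 0.77 ± 0.09, Trim71 (8) fell by 0.56 ± 0.06 and Lrrc58 (6) fell by 0.29 ± 0.05 in iNs, and these 3 did not pass in ESCs. Tnrc6a (8) and Ankrd52 (6) rose by 0.20 ± 0.06 and 0.21 ± 0.06 in iNs, calls lost in some alternatives. Crebrf (6) rose by 0.83 ± 0.08 and Csnk1a1 (6) did not pass.

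**Figure D5:**
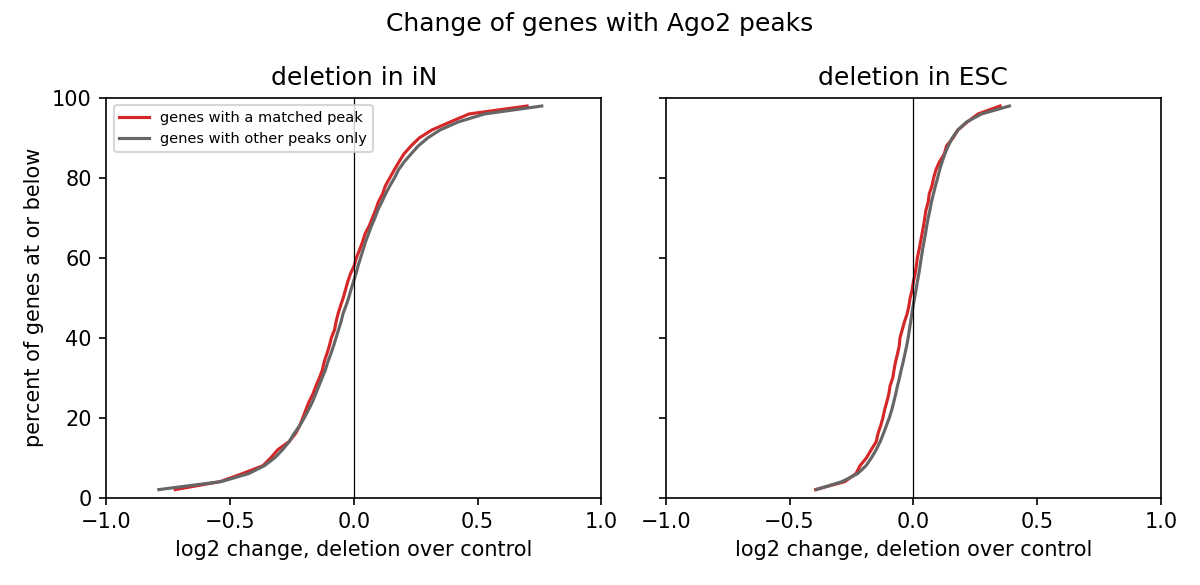
Cumulative percent of genes against log2 change with the deletion in iNs and ESCs (n = 3 per group), for genes with a region matched to a cluster microRNA (red) and genes with other Ago2 regions only (grey).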

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

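The explanations by a higher level of the host transcripts in cis and, for cholesterol synthesis genes, by a step further along the path from stem cell to neuron were chosen after seeing the results they explain. So was the choice of regroupings for the interaction. For pluripotency microRNAs the step along the path was written down beforehand.

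Upstream microRNAs were higher with the deletion in iNs, a list call lost with an estimated correlation (0.291). Their median log2 change exceeded that of 358 other microRNAs outside the cluster (0.04) by 0.19 (bootstrap interval −0.08 to 0.43). A true rise and a rise in share after loss of the cluster's reads thus cannot be told apart. The interval resamples microRNAs, not libraries, and arms of 1 hairpin are not independent. Scaled to all features of the file, the upstream median was −0.03, as scaling to the microRNA total alone would give. Meg3 was higher by 0.56 and Rian by 0.27 in the RNA libraries, so a higher level of the host transcripts in cis may also contribute. SnoRNAs of the imprinted domain did not rise with them: 8 of 10 fell in the small RNA libraries (median −0.86). Other snoRNAs fell by as much (median −0.94), so this does not decide the question.

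Cholesterol synthesis genes were lower with the deletion in iNs (median −0.54), a list call lost with an estimated correlation (0.193). They rose by 2.20 from ESCs to iNs, against the direction seen with the deletion. A step further along that path would move them up only if they rise steadily, which day 0 and day 10 alone cannot show. Whether the higher Neurog2 level carries cells further along it was not tested. Without mitochondrial, 7S and ribosomal-RNA-like genes the median was −0.54, and with each library left out it lay between −0.59 and −0.51. The highest deletion library lay 0.44 below the lowest control (difference −0.44 in mean log2 CPM of the list), and a medium or handling that differed between the cultures cannot be told apart from the genotype.

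Pluripotency microRNAs were lower with the deletion in iNs, a list call lost with an estimated correlation (0.512). Fewer leftover stem cells would lower stem cell genes too. The 200 genes with the largest fall from ESCs to iNs had a median of 0.18 (0.07 to 0.30) with the deletion and proliferation genes one of 0.06. Control ESC libraries and control iN library A chose the 200 genes, the other iN libraries gave their median, and the interval resamples genes, not libraries. Genes near the floor could pass the filter through deletion libraries alone, which would raise that median, so fewer leftover stem cells stay open. The pluripotency gene list went the other way, with 8 of 14 lower, 2 higher and a median of −0.77 (not called with an estimated correlation, 0.193). Scaled to all features the list's median was −1.34. A step further along the path would part the genes that rise from those that fall, whose medians differed by −0.06 (−0.19 to 0.05). The same filter and libraries were used, so this difference has the same limit.

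The deletion's effect differed between iNs and ESCs, tested as an interaction, for 2473 genes and 30 microRNAs. Among lists, the median log2 difference was 0.74 for Dlk1-Dio3 domain genes, 0.34 for glutamatergic synapse genes, 0.11 for ion channel genes, −0.48 for p53 and stress genes and −0.74 for cholesterol synthesis genes. With an estimated correlation the first 3 were not called (adjusted p of 0.179, 0.252 and 0.268 with camera and Benjamini-Hochberg correction, 12 libraries). It was 0.45 for upstream microRNAs and 0.54 for neuronal microRNAs (0.04 and 0.12 scaled to all features) and −0.56 for pluripotency microRNAs, and none of these 3 was called with an estimated correlation (0.11, 0.11 and 0.694). Genes that differed upward were Txnip (3.08), Cpt1a (2.42), B830012L14Rik (1.5), Neurog2 (1.35), Slc17a6 (1.29), Meg3 (0.92), Kcnq3 (0.75) and Rian (0.64). Genes that differed downward were Msmo1 (−0.86), Dlk1 (−0.95), Mvd (−1.06), Atf5 (−1.43), Chac1 (−2.29), Slc7a3 (−3.60), Phgdh (−3.74) and Cth (−4.87). MicroRNAs that differed were miR-433-3p (1.42), miR-9-3p (0.90), miR-136-3p (0.76), miR-9-5p (0.59), miR-292a-5p (−1.14), miR-106a-5p (−1.25), miR-291a-5p (−1.27) and miR-20b-5p (−1.5). The calls of Slc17a6, miR-433-3p, miR-9-3p, miR-136-3p and miR-9-5p were lost in some alternatives.

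Reads outside the microRNAs, which no fixed comparison used, held a larger share of deletion iN small RNA counts than of controls: mitochondrial rRNA 6.19%, mitochondrial tRNA 8.23%, Y RNA 3.75% and the ribosomal-RNA-like CT010467.1 12.5%. The share of snoRNA went the other way (14.1 to 10.6%), and CT010467.1 did not pass when tested among non-microRNA genes (log2 fold change 0.19).

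The labels of the 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. For microRNAs, 1 of 10 splits (the real one) gave as many as the real 448, 178 and 73 (iNs against ESCs, deletion in iNs, deletion in ESCs), and the highest other split gave 0 each. For genes, 1 of 10 gave as many as 15352, 4109 and 309, with 0, 0 and 1 for the highest other. For lists of microRNAs, 8, 6 and 6 of 10 gave as many as the real 5, 4 and 2, with 8, 5 and 4 for the highest other. For lists of genes, 6, 1 and 1 of 10 gave as many as 12, 10 and 7, with 13, 5 and 3 for the highest other. For the interaction 100 regroupings were drawn, and those that kept the true genotype groups of 1 cell type carry the real effect. Counting only the real grouping and those that mixed both cell types, 1 of 82 gave as many genes as 2473 (highest other 6) and 1 of 79 as many microRNAs as 30 (highest other 0). A grouping that mixes genotypes holds the genotype difference as spread within its groups, which lowers its count. The same is so for the other splits of 6 libraries. Low counts in them thus cannot show how many calls chance alone would give. Of all 100 drawn, 1 gave as many genes (highest other 1518) and 3 as many microRNAs (highest other 132). As many lists as the real 5 came from 3 of 82 for genes (highest other 5), against 13 of all 100 drawn. As many as the real 3 came from 23 of 79 for microRNAs (highest other 4), against 36 of all 100 drawn, as often as a random grouping would give.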

How the results depend on the processing

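Posterior mean counts, copies kept apart, scaling without cluster microRNAs, removal of mitochondrial, 7S and ribosomal-RNA-like genes, lists without Mirg and 2 target backgrounds were chosen after seeing the results. MicroRNA counts in the ESC deletion (73) became 118 without the filter and 179 with a replicate block, and the RNA count (309) became 504 and 1019, and 90 to 315 with 1 library left out. The small RNA interaction (30) became 56 with DESeq2 and 17 to 37 with 1 library left out. With an estimated correlation the lists called went from 5 to 0, 4 to 1 and 2 to 1 for microRNAs (iNs against ESCs, deletion in iNs, in ESCs), 12 to 3, 10 to 0 and 7 to 2 for genes, and 5 to 2 and 3 to 0 for the interactions. With a replicate block the microRNA lists in the ESC deletion went from 2 to 1 (Sfmbt2 intron lost), though same-letter libraries there had r of 0.536, 0.031 and 0.362. With a block the glial list in the iN deletion had an adjusted p of 0.0501 (camera) and was no longer called. The target difference in ESCs (−0.019) passed, unadjusted over the settings tried, with stricter peaks (−0.041) and with 2 or more matched peaks (−0.059). It was −0.041 to 0.006 with 1 library left out, reversed without deletion ESC library A. Both peak lists hold the same regions, so an overlap of 100% was fixed. It was 60.6% between regions above each list's median fold. Other causes were not tested. In iNs the target difference (−0.022) was −0.036 to −0.002 with 1 library left out. Of 6786 alternative values of named genes, 6247 kept their call, 532 lost it, 7 gained one and 0 reversed.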

Other observations

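The comparison of host transcripts with upstream microRNAs and that of Neurog2 with the path to neurons were chosen after seeing the results.

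Neurons without the cluster had lower RNA of cholesterol synthesis genes (a list call lost with an estimated correlation, 0.193), of Phgdh and of Cth, and higher Txnip and Neurog2.

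A difference in medium or handling between cultures stays open beside an effect of the deletion for the lower cholesterol synthesis genes. It stays open too for Phgdh, Cth, Txnip and Neurog2. For the cholesterol list the deletion libraries lay below the controls (difference −0.44), which either could give. Control and deletion iNs induced side by side in 1 batch of medium, with lipids and serine measured in it, could separate this from the genotype.

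The rise of upstream microRNAs may come from the host transcripts in cis (Meg3 0.56, though snoRNAs of the domain fell) or from scaling (median −0.03 with all features). Small RNA-seq with spiked-in RNA of known amount, or northern blots of miR-540-3p and miR-1188-5p, could tell these apart.

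The fall of pluripotency microRNAs in iNs (median −1.34 with all features) came with lower pluripotency genes (median −0.77), both list calls lost with an estimated correlation (0.512 and 0.193), but not with a fall of the 200 genes that fell most from ESCs to iNs (median 0.18). The filter may have raised that last median for genes near the floor, so fewer leftover stem cells stay open. Part of the stem cell program may have been shut down further in deletion cells. A time course of miR-302d-3p and its host RNA from day 0 to day 10 could test this.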
